A study of Mus musculus with 15 samples.

How the data were processed

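Total RNA of neonatal mouse brains was sequenced in 15 libraries (4 WT, 4 P1KO, 4 P2KO and 3 NdcKO), prepared with a stranded TruSeq messenger RNA kit and run on an Illumina sequencer per the labels. The submitters' processing notes name TopHat2 for alignment to mm10 and Cufflinks with Cuffdiff for levels and tests, without versions or settings. The authors deposited 6 tables, 1 for each pair of groups, which hold only genes that Cuffdiff called significant. The FPKM values in them are, per the file headers and as deposited by the authors, 1 level per group, pooled over its libraries by the Cuffdiff model. The log2 fold change in each table was deposited by the authors and equals the log2 ratio of both deposited levels, which was checked for every listed gene with levels above 0 (largest gap 1.33e-05). The p-value and q-value of each gene were deposited by the authors from Cuffdiff, and they are the only measure of the spread between libraries used here. The smallest p-value in the deposited tables was 5e-05, shared by 15653 entries with a q-value of 0.00028, so that genes at this value are not ranked by it. The relation of p to q implies about 87635 tests over the 6 tables, or 14606 per comparison.

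Read depth is unknown, and whole read counts cannot be recovered from pooled FPKM, so the precision of low levels was not computed. No spread, leave-one-out result or model across libraries could be computed either, because no value per library was used. A gene missing from a table may have been tested without passing or not tested, and a count adjusted over a gene list alone could not be made, since unlisted members have no p-value. Levels of the 9394 listed genes were collected from all tables (34465 levels of genes in groups, 0 of them different between tables), so that a fold could also be computed for genes listed elsewhere. In each of the NdcKO tables, dates stood in place of 13 gene symbols and were left as they stood, and 1 line without values was not used here.

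Signs were turned where needed, so that every fold is given as knockout over WT, P1KO over P2KO, or NdcKO over a single knockout. The gene lists, the comparisons, Fisher's exact test of the lists and the rule for naming genes were chosen before the data were examined, unlike the tests described below as chosen or added later and those of GC content, of agreement between the NdcKO tables, of the window around Pum1 and of sex-linked genes. The rule names, per table, Pum1 and Pum2 wherever listed, and the 10 highest and 10 lowest finite folds with the higher group at 1 FPKM or more, leaving out small RNA genes, provisional symbols and entries of several genes. It also names up to 4 listed members per gene list with the largest absolute folds, and the 10 genes with the largest smallest absolute fold among those with one direction in all 3 knockouts or in both single knockouts. Genes outside the rule are said to be chosen after their values were seen.

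The 34 lists were targeted genes, neural stem and progenitor cell, cell cycle, cyclin-dependent kinase inhibitor, neuron, synapse and glutamate or GABA receptor, astrocyte, oligodendrocyte lineage, microglia, endothelium, mural, fibroblast and meninges, erythroid, choroid plexus and ependyma, muscle, bone and skin, forebrain region, midbrain, hindbrain and cerebellum region, hypothalamus and pituitary, immediate early, heat shock and unfolded protein, hypoxia and glycolysis, cholesterol synthesis, p53 target, interferon response, Pumilio partners and mRNA decay, textbook Pumilio targets, X inactivation and Y chromosome, cytosolic ribosomal proteins, nuclear-encoded mitochondrial oxidative phosphorylation, mitochondrial ribosome, replication-dependent histones, small RNA genes, protocadherin clusters, zinc finger proteins and Hox clusters. Lists with at least 5 listed members in a table were tested with a two-sided Fisher's exact test of members higher or lower against the other listed genes. P-values were adjusted by the Benjamini-Hochberg method over the lists of a table, with a threshold of 0.05. Genes are not independent replicates, and these tests do not carry the variation between animals.

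As an alternative chosen after seeing the data, the median log2 fold change of each list, over members with at least 1 FPKM in both groups, was set against 10000 random lists matched in 8 bins of GC content and 5 bins of length. GC content and length came from the longest protein-coding GENCODE M21 transcript of each gene, or its longest transcript where none was protein-coding. They were found for 9317 genes (99.2%). A permutation p of 0.0002 is the smallest these draws can give. Alternatives set in advance were q of at most 0.01, at least 1 FPKM in the higher group, at least a 2-fold difference, a pseudocount of 1 with a minimum of 0.5 on the log2 scale, direction against the table's median, genes at 0 in a group left out, and matching of genes by symbol and locus. Added later were direction against the median of all levels, a contrast without shared libraries, a background of 14606 genes for the overlap, and the textbook targets without Pum1 and Pum2.

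The overlap of both single knockouts was compared with independent lists and with 200 simulations of unchanged groups that share their controls. Intervals of shares are exact 95% Clopper-Pearson intervals over genes. For ribosomal protein and oxidative phosphorylation genes in P2KO, the 20 nearest other genes in length and GC content were also used, chosen after seeing the data, with intervals from 10000 redraws of members and matches for these and for the bins. The median absolute log2 fold change of P1KO over WT was compared with that of NdcKO over WT over 7086 genes, with an interval from 1000 redraws of genes. Listed genes within 20 Mb of Pum1 or Pum2 were counted against genes not listed in the same table, at the positions in the deposited tables and, chosen after seeing the data, over genes on the same chromosome in GENCODE M21. For the Pumilio motif TGTANATA, log2 fold changes clipped at 3 were regressed on its presence in annotated 3' UTRs of at least 50 bases, with GC content and lengths as covariates, and the coefficient was ranked among those of 200 motifs with the same letters in another order.

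Without noise in the controls the overlap simulation gave one direction for 50.7% of shared genes. The list test was tested on simulated data with 85% of a list's members set higher. It found the planted list in 14 of 20 repeats with 391 genes and in 20 of 20 with 8211 genes, and called 0 of 40 and 0 of 540 other lists. The matched test found a list shifted by 0.3 in 20 of 20 repeats and called 5 of 480 others. A motif shift of 0.1 gave a mean estimate of 0.102 over 20 repeats, and 1 of 20 unshifted repeats ranked above 95% of the reordered motifs. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.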

Results

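Messenger RNA was sequenced from neonatal mouse brains of 4 genotypes, in 15 libraries. Pum1 and Pum2 encode the Pumilio proteins, which bind a short sequence in the 3' untranslated regions (UTRs) of messenger RNAs and lower their translation or stability. The groups were labelled as wild-type brains (WT, 4 libraries), brains of animals with a global Pum1 knockout (P1KO, 4 libraries), brains of animals with a global Pum2 knockout (P2KO, 4 libraries) and brains with a knockout of both genes by Nestin-Cre, a recombinase expressed in neural progenitors (NdcKO, 3 libraries). The study asked whether the Pumilio proteins change the RNA levels of their targets. The WT, P1KO and P2KO brains shared material with an experiment that mapped the RNA sites bound by the proteins, whereas the NdcKO brains were collected in addition, so each comparison with NdcKO was also a comparison between collections.

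For each pair of groups the authors deposited a table of the genes that passed their test, with 1 pooled level per group in FPKM (fragments scaled to transcript length and to the mapped fragments of the library) and a q-value. The 6 tables listed 9394 genes, of which 7328 had a level in all 4 groups. Because the tables hold no value per library, no spread between libraries stands beside any level here, the error behind each call is the one in the authors' q-value, and the depth of the libraries is unknown. Genes are not independent replicates, which limits every test on gene lists below.

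The levels of the targeted genes were examined first. Pum1 (mm10, chromosome 4, 130663359 to 130781565) was lower in both groups labelled as lacking it. The authors' deposited table gave Pum1 at 8.63 FPKM in P1KO and 25.5 FPKM in WT, a log2 fold change of -1.56 (q = 0.00028), or 33.9% of the WT level. In NdcKO, Pum1 stood at 6.78 FPKM in the authors' deposited table, a log2 fold change of -1.91 against WT (q = 0.00028). Pum1 was not listed for P2KO against WT, where its pooled levels in the authors' deposited tables were 27.0 and 25.5 FPKM.

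Pum2 (chromosome 12, 8674134 to 8752583) was not lower in any group. The authors' deposited tables gave 32.6 FPKM in WT, 34.1 FPKM in P2KO, 50.3 FPKM in P1KO and 69.8 FPKM in NdcKO. Pum2 was not listed for P2KO against WT, and it rose in P1KO by 0.63 and in NdcKO by 1.10 on the log2 scale of the authors' deposited tables (both q = 0.00028). It was also higher in NdcKO than in P1KO in the authors' deposited table, by 0.47 on the log2 scale (q = 0.00568). The Pum2 level therefore does not check the P2KO and NdcKO labels, and these groups are named below as brains labelled P2KO or NdcKO. The rises of Pum2 in NdcKO do not show a change specific to this gene. Its transcript GC content is 42.2%. Over WT, genes near that GC content (median 42.6%) had a median log2 fold change of 0.87 in NdcKO (quartiles 0.55 and 1.25). Over P1KO, such genes (median 42.7%) had a median of 0.84 in NdcKO (quartiles 0.55 and 1.28), above the 0.47 of Pum2. A level pooled over a whole gene does not show whether single exons were missing, and the alleles are not described in the sources used here.

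**Figure D1:**
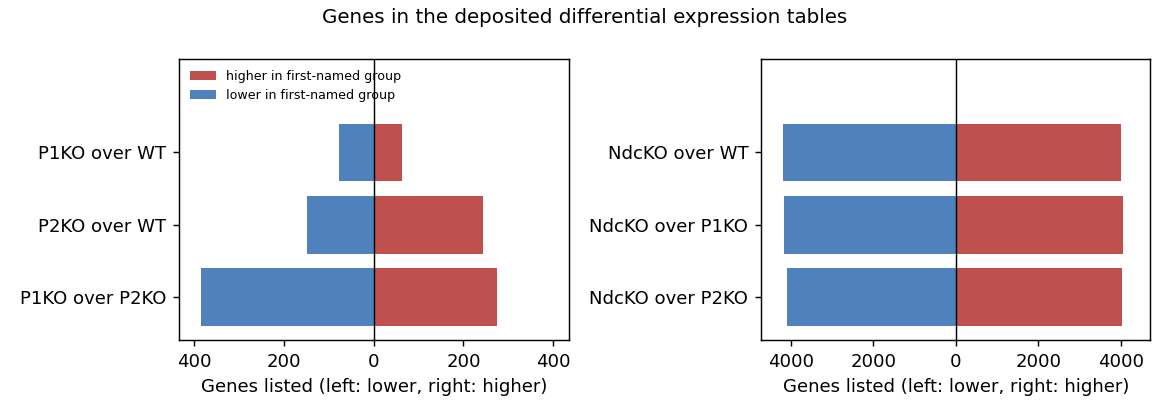
Number of genes in each deposited table (x axis, number of genes), drawn to the right of 0 where the first-named group was higher and to the left where it was lower, with a different scale in each panel. Tables without NdcKO (left) listed 139 to 661 genes, and tables with NdcKO (right) listed 8115 to 8216 genes.

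The comparison of P1KO with WT addressed the loss of Pum1. Few genes differed, and markers of the choroid plexus, the epithelium that makes cerebrospinal fluid, were lower in P1KO. The authors' deposited table gave log2 fold changes of -1.16 for Kcne2, a potassium channel subunit, -1.02 for Ttr, the carrier of thyroxine, -0.97 for Folr1, a folate receptor, and -0.77 for Clic6, a chloride channel family member. Cdkn1b, a cyclin-dependent kinase inhibitor, and Slbp, the histone stem-loop binding protein, both textbook Pumilio targets, rose by 0.40 (q = 0.0132) and 0.47 (q = 0.0026) on the log2 scale of the authors' deposited table. The list of these targets had 4 listed members, 3 of them higher, too few for the exact test. The lower member was Pum1 itself, and Pum2 was among the higher ones. The list did not pass against random lists matched on GC content and length (adjusted permutation p = 0.188). Without Pum1 and Pum2, 9 of 10 members with levels were higher, at an unadjusted permutation p of 0.12. Genes of the Y chromosome were higher and Xist, the RNA that silences an X chromosome, was lower in P1KO.

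In total 139 genes were listed, 62 higher and 77 lower in P1KO. All 5 listed members of the choroid plexus and ependyma list were lower, but with so few members the direction did not pass Fisher's exact test against the other listed genes (p = 0.0652, adjusted p = 0.13 over the 2 lists tested). When the list's median over all members with a level, listed or not, was set against 10000 random lists matched on transcript GC content and length, the adjusted permutation p was 0.0013, with a median log2 fold change of -0.87 over 6 members. Of the X inactivation and Y chromosome list 4 of 5 listed members were higher (adjusted exact p = 0.172, and permutation p = 0.0013 against matched lists). Altogether 7 lists passed against matched lists, with smaller shifts for the other 5. Lower in pooled level were all 8 cholesterol synthesis genes (median log2 fold change -0.19, adjusted permutation p = 0.0013), 61 of 71 cytosolic ribosomal protein genes (-0.08, 0.0013), all 10 mural cell, fibroblast and meningeal markers (-0.14, 0.00416) and 12 of 15 cell cycle genes (-0.08, 0.0342). The authors' test listed 1 of the mural cell, fibroblast and meningeal markers. It listed 0 cholesterol synthesis, 0 cytosolic ribosomal protein and 0 cell cycle genes. Of the midbrain, hindbrain and cerebellum genes 5 of 7 with levels were higher (0.17, adjusted permutation p = 0.00867), but the 1 listed member, Pax2, was lower, at a log2 fold change of -0.53 in the authors' deposited table. The authors' deposited table gave log2 fold changes of 1.25 for Eif2s3y, 1.09 for Ddx3y, 0.95 for Uty and -0.86 for Xist.

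Among the other P1KO genes were RNA components of ribonucleoproteins. The authors' deposited table gave log2 fold changes of 1.87 for Rpph1, the RNA of ribonuclease P, 1.74 for Rmrp, the RNA of the mitochondrial RNA-processing endoribonuclease, and 1.66 for Rn45s, the ribosomal RNA precursor. These RNAs lack the long poly(A) tails by which messenger RNA is selected. Foxd3, a neural crest transcription factor, and Edn1, the endothelin 1 precursor, rose by 1.45 and 1.09 on the log2 scale of the authors' deposited table. Gas1, a growth arrest protein of neural progenitors, was higher by 0.57 and Mobp, a myelin protein, had a log2 fold change of -0.93 there. In the authors' deposited table the largest finite decreases were those of Smim22 (-2.29), the defensin Defb11 (-1.82) and Pum1 itself, followed by Prr32 (-1.26), all on the log2 scale and among genes of 1 FPKM or more. The growth hormone gene Gh and the microRNA gene Mir6389 were listed at 0 in P1KO.

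Genes near Pum1 were over-represented in the P1KO table. Of the 138 listed genes other than Pum1, 16 lay within 20 Mb of it on chromosome 4, 3 of them higher and 13 lower in P1KO (odds ratio = 4.27 by a two-sided Fisher's exact test against genes not listed in this table, p = 5.53e-06, adjusted p = 6.63e-05 over the 12 windows and tables tested). For P2KO the same window held 8 of 391 listed genes (odds ratio = 0.641, exact p = 0.295). For P1KO against P2KO it held 19 listed genes and was not over-represented either (odds ratio = 0.919, exact p = 0.816). Positions were those in the authors' tables, but 2 of the 16 genes lie on other chromosomes in GENCODE M21 and 1 is not in it; over genes on the same chromosome in both, 13 listed genes lay in the window (odds ratio = 3.6, exact p = 0.000187). The window genes named here were chosen after their values were seen. The authors' deposited table gave log2 fold changes of -2.11 for Sfn, an epithelial 14-3-3 protein, -1.14 for 1700003M07Rik, -0.73 for the small nucleolar RNA host gene Snhg3 and 0.41 for the transcription factor Foxo6. Within 20 Mb of Pum2, P1KO against P2KO listed 10 genes, 2 higher and 8 lower in P1KO (odds ratio = 2.62, adjusted exact p = 0.0378). P2KO against WT listed 5 there, all higher (odds ratio = 2.07, exact p = 0.109), and P1KO against WT listed 0. For NdcKO against WT listed genes were under-represented near Pum2 (odds ratio = 0.402, adjusted exact p = 0.019).

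**Figure D2:**
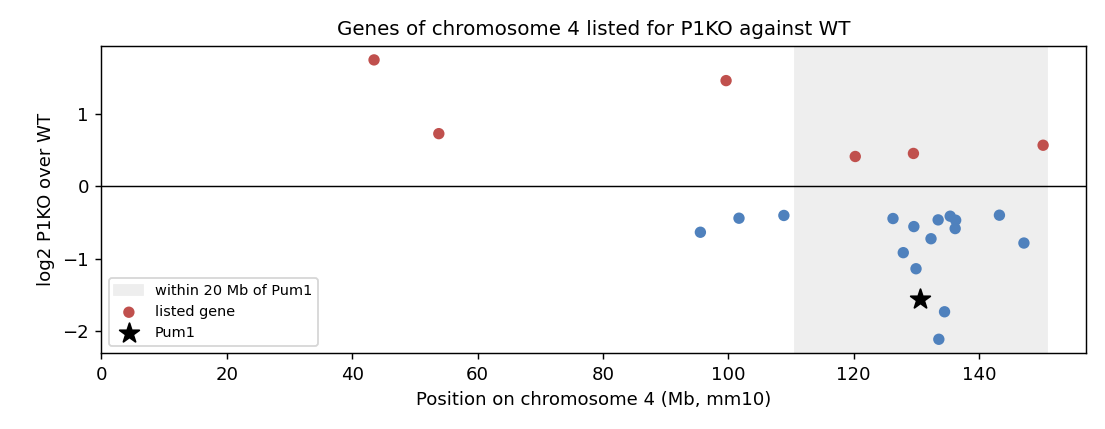
Genes of chromosome 4 listed for P1KO against WT, by position (x axis, megabases, mm10) and log2 fold change of P1KO over WT (y axis), with the region within 20 Mb of Pum1 shaded and Pum1 drawn as a star. The shaded region holds 16 listed genes besides Pum1, 13 of them below 0.

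Comparing brains labelled P2KO with WT gave 391 listed genes, 243 higher and 148 lower. Ribosomal proteins and nuclear-encoded subunits of oxidative phosphorylation were higher by small amounts. The authors' deposited table gave log2 fold changes of 0.61 for Rpl37 and 0.55 for Rps14, proteins of the large and small ribosomal subunits, and of 0.53 for Cox7a2 and 0.49 for Cox7b, subunits of cytochrome c oxidase. All 4 listed members of the hypothalamus and pituitary list, hormone genes of the pituitary below the brain, were far higher, at log2 fold changes in the authors' deposited table of 4.82 for Gh, 4.33 for Cga, the common subunit of glycoprotein hormones, 4.10 for Pomc, the corticotropin precursor, and 4.07 for Tshb, a thyrotropin subunit. Lhb, a subunit of luteinizing hormone, was not listed for P2KO, at 0.819 FPKM against 0.793 FPKM in WT in the authors' deposited tables. Against matched lists the adjusted permutation p was 0.0454, over 5 list members with at least 1 FPKM in both groups. Their median log2 fold change was 0.33. Cga, Tshb and Lhb, under 1 FPKM in WT, were not among them, so this p does not test the rise of the pituitary hormone genes. Markers of oligodendrocytes, endothelium and choroid plexus were lower.

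All 33 listed cytosolic ribosomal protein genes were higher (Fisher's exact test against the other listed genes, adjusted p = 2.16e-07 over the 3 lists tested), as were all 21 listed oxidative phosphorylation genes (adjusted p = 5.66e-05). Of 8 listed zinc finger protein genes 7 were lower (adjusted p = 0.00552), among them Zfp771 with a log2 fold change of -0.56 and Zfp759 with -0.54 in the authors' deposited table. Because most listed genes were higher, the direction was also taken against the table's median log2 fold change of 0.38, which left 195 of 391 genes higher. The ribosomal call then held in the exact test (adjusted p = 0.0297), and the oxidative phosphorylation and zinc finger calls did not (adjusted p = 0.655 and 0.101). Against random lists matched on GC content and length both passed (adjusted permutation p = 0.000625), with 67 of 70 oxidative phosphorylation genes higher and 138 of 200 zinc finger genes lower. Over all genes with levels, listed or not, the median log2 fold change of P2KO over WT was -0.01. Transcript length moved with this comparison, since listed genes that were higher had a median length of 1129 bases and those that were lower of 2761 bases (Spearman's rho = -0.334 across genes).

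The lists with fewer than 5 listed members could not be tested by direction alone. All 4 listed choroid plexus markers were lower, with log2 fold changes in the authors' deposited table of -0.64 for Clic6, -0.56 for Folr1 and -0.55 for Kcne2. All 4 listed endothelial markers were lower, among them the vascular endothelial growth factor receptors Flt1 (-0.48) and Kdr (-0.40), on the log2 scale of the authors' deposited table. The authors' deposited table also gave lower levels of all 4 listed oligodendrocyte genes, with log2 fold changes of -1.48 for Mobp, -0.53 for Gpr17, -0.51 for Mbp and -0.41 for Olig1. Against random lists matched on GC content and length the adjusted permutation p was 0.000625 for choroid plexus, 0.000625 for endothelium and 0.0075 for the oligodendrocyte lineage, over 6, 9 and 9 members with levels. Also lower by this test were midbrain, hindbrain and cerebellum genes (0.0075), mural cell, fibroblast and meningeal markers (0.0105), progenitor markers (0.0283) and histones (0.000625). Higher than matched genes were synapse and receptor genes (0.0438), small RNA genes (0.000625) and genes of X inactivation and the Y chromosome (0.000625). Of the synapse and receptor genes only 9 of 16 were higher, at a median log2 fold change of 0.03 against -0.04 for matched genes. Their 1 listed member, Shank1, was lower, at -0.40 in the authors' deposited table. The progenitor genes Sox3 and Nes had log2 fold changes of -1.05 and -0.38 in the authors' deposited table.

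Several other genes stood out in brains labelled P2KO. Among the lowest folds in the authors' deposited table were the protease genes Cpa3 (-1.73), Cma1 (-1.52) and Tpsb2 (-1.38), on the log2 scale and from WT levels between 1.06 and 1.55 FPKM. The authors' deposited table gave a log2 fold change of -2.62 for Erdr1, a gene listed on the Y chromosome, and of -1.46 for Gt(ROSA)26Sor, the transcript of a locus often used to insert transgenes. Dynlt1b, a dynein light chain with near-identical copies, rose by 1.46, and Rec8, a meiotic cohesin, by 1.62 on the log2 scale of the authors' deposited table. How reads shared between Dynlt1b and its copies were assigned is not given in the sources used here.

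**Figure D3:**
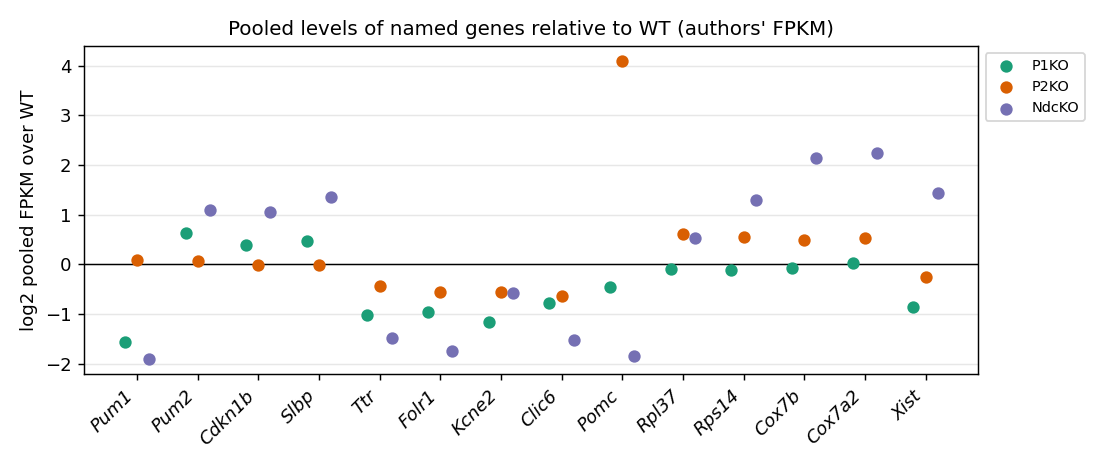
Log2 of the authors' pooled FPKM of P1KO, P2KO or NdcKO over WT (y axis) for 14 named genes (x axis), 1 point per group and gene and without error bars, because no value per library was available to this work. Pum1 lies at -1.56 in P1KO and -1.91 in NdcKO, and Pomc at 4.10 in P2KO.

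Direct comparison of the single knockouts, P1KO over brains labelled P2KO, listed 661 genes, 275 higher and 386 lower in P1KO. All 50 listed ribosomal protein genes were lower in P1KO (Fisher's exact test, adjusted p = 4e-12 over the 6 lists tested), for example Rps12 with a log2 fold change of -0.75 and Rpl37 with -0.69 in the authors' deposited table. All 26 listed oxidative phosphorylation genes were lower as well (adjusted exact p = 3.62e-06), a call that ended against the table's median (adjusted p = 0.32) and held against matched random lists, with 68 of 70 members lower (adjusted permutation p = 0.0026). The authors' deposited table gave log2 fold changes of -4.73 for Tshb and -4.56 for Pomc, and Gh was listed at 0 in P1KO and at 149 FPKM in P2KO. Textbook Pumilio targets were higher in P1KO for 4 of 5 listed members (adjusted exact p = 0.2), including Pum2 (0.56), Slbp (0.48) and Cdkn1b (0.41) on the log2 scale of the authors' deposited table. The lower member was Pum1 itself. Without Pum1 and Pum2, 8 of 11 targets with levels were higher, at an unadjusted permutation p against matched lists of 0.417. The progenitor transcription factors Sox2 and Sox3 were higher in P1KO by 0.61 and 1.09 in the authors' deposited table.

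The calls of both single knockouts against WT were then set side by side. The tables shared 43 genes, 33 with one direction (14 higher and 19 lower) and 10 with opposite directions. Independent lists of these sizes drawn from the 9394 genes would share 1.6 genes that are higher and 1.21 that are lower. That expectation leaves out the WT libraries, which both tables use. In a simulation of unchanged groups compared with 1 control, chance differences of the control gave a mean of 26.7 shared genes (11 to 44 over 200 simulations), with 100% in one direction. Since no value per library was available to this work, the WT libraries could not be split between the comparisons, and part of the overlap may come from them. Among the shared genes the authors' deposited tables gave higher levels in P1KO and P2KO of Rmrp (log2 fold changes of 1.74 and 2.73), Rpph1 (1.87 and 2.73) and Eif2s3y (1.25 and 0.98), and lower levels of Prr32 (-1.26 and -0.91), Kcne2 (-1.16 and -0.55) and Mobp (-0.93 and -1.48).

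Brains labelled NdcKO differed from WT in 8211 listed genes, 4013 higher and 4198 lower. Nuclear-encoded oxidative phosphorylation genes and both kinds of ribosomal protein genes were higher, with log2 fold changes in the authors' deposited table of 2.41 for Ndufs4, a complex I subunit, 2.39 for Uqcrh, a complex III subunit, 2.54 for Mrpl33, a mitochondrial ribosomal protein, and 2.67 for Rps27a. Among textbook Pumilio targets, a list that did not pass its test (adjusted exact p = 0.0555), Cks2, a cyclin-dependent kinase subunit (2.13), Snca, alpha-synuclein (2.09), Ccne2, cyclin E2 (1.91), and Cdkn1b (1.06) were higher, on the log2 scale of the authors' deposited table. Neural progenitor and endothelial markers were lower, with log2 fold changes in the authors' deposited table of -1.93 for Notch1, -1.49 for Msi1, -1.89 for Vwf and -1.87 for Tie1. Transcript GC content moved with this comparison: Spearman's rho between GC content and log2 fold change was -0.715 across the 8127 listed genes with GC content, and the median GC content was 45.1% for genes that were higher and 55.8% for those that were lower. The rho was -0.0542 in P1KO and -0.202 in P2KO. Over all genes with levels of 1 FPKM or more in both groups the median log2 fold change was -0.37; with direction taken against it, 4049 listed genes were higher.

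**Figure D4:**
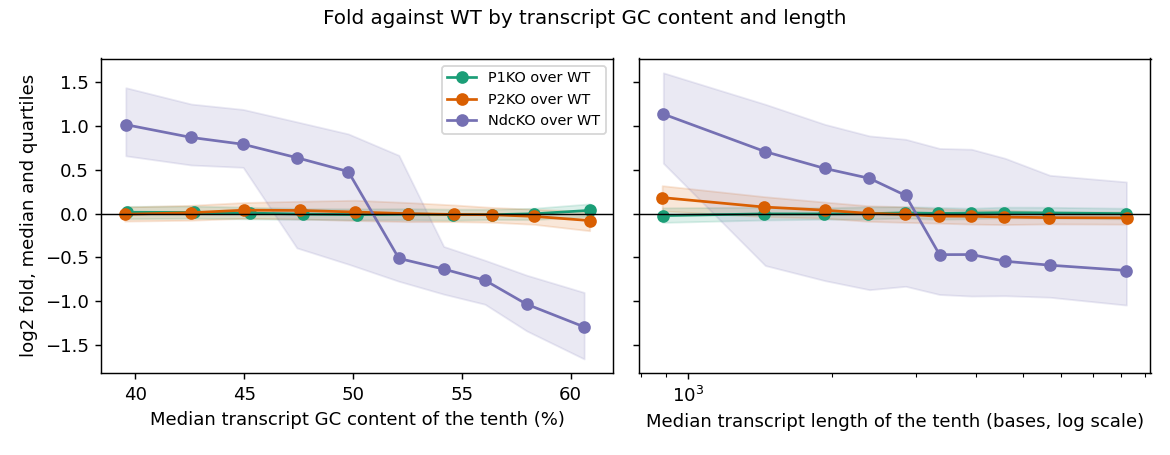
Median log2 fold change against WT (y axis, with quartiles shaded) in 10 equal groups of genes ordered by transcript GC content (left, x axis in percent) or transcript length (right, x axis in bases, log scale), for genes with levels of at least 1 FPKM in both groups. For NdcKO the median falls with GC content, whereas P1KO stays near 0 and P2KO is higher among short transcripts.

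In NdcKO, 28 lists had at least 5 listed members and 9 passed Fisher's exact test after adjustment. Higher were oxidative phosphorylation genes (67 of 71, adjusted exact p = 2.35e-15), mitochondrial ribosome genes (64 of 68, adjusted p = 1.62e-14), cytosolic ribosomal protein genes (57 of 66, adjusted p = 1.88e-09), zinc finger protein genes (144 of 225, adjusted p = 3.54e-05) and interferon response genes (6 of 6, adjusted p = 0.0476). Lower were endothelial markers (10 of 10, adjusted exact p = 0.0111), neural stem and progenitor markers (14 of 16, adjusted p = 0.02), mural cell, fibroblast and meningeal markers (10 of 11, adjusted p = 0.0475) and replication-dependent histones (7 of 7, adjusted p = 0.049). Because GC content moved with the comparison, each list was also set against random lists matched on GC content and length. Then 4 of the 23 lists with enough members passed, namely oxidative phosphorylation (higher, adjusted permutation p = 0.0023), choroid plexus (lower, 0.0023), endothelium (lower, 0.0123) and cholesterol synthesis (lower, 0.0287). The adjusted permutation p was 0.0543 for the mitochondrial ribosome, 0.502 for cytosolic ribosomal proteins, 0.497 for zinc finger proteins, 0.33 for progenitor markers and 0.0802 for mural cells, fibroblasts and meninges. The interferon and histone lists had too few members with levels for this, and their calls also ended with direction against the table's median (adjusted exact p = 0.0794 and 0.0545).

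Examples of these groups in the authors' deposited table were the meningeal collagen gene Col1a1 at a log2 fold change of -1.94 and the cholesterol synthesis genes Mvk and Dhcr24 at -1.36 and -1.35. The authors' deposited table listed Ttr, Folr1 and Foxj1, markers of choroid plexus and ciliated ependyma, at log2 fold changes of -1.48, -1.73 and -1.75. Fabp7, a fatty acid binding protein of radial glia, was among the 2 progenitor markers that were higher, at 1.48 in the authors' deposited table. Of the textbook Pumilio targets 10 of 12 were higher (adjusted exact p = 0.0555), and 9 of 10 once Pum1 and Pum2 themselves were left out (adjusted p = 0.0404). Against matched random lists the adjusted permutation p was 0.266, and the unadjusted p = 0.328 without Pum1 and Pum2, so their rise was not told apart from that of other genes with like GC content and length.

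The other lists tested in NdcKO did not pass. Higher members were 8 of 16 for the cell cycle (adjusted exact p = 1), 6 of 18 for neurons (0.373), 6 of 16 for synapses and glutamate or GABA receptors (0.58), 3 of 8 for astrocytes (0.782), 2 of 12 for the oligodendrocyte lineage (0.084) and 4 of 10 for microglia (0.782). The counts were 3 of 5 for muscle, bone and skin (0.762), 1 of 8 for forebrain genes (0.132), 0 of 6 for choroid plexus and ependyma (0.0733), 0 of 6 for midbrain, hindbrain and cerebellum (0.0733) and 1 of 5 for hypothalamus and pituitary (0.501). For immediate early genes they were 1 of 8 (0.132), for heat shock and unfolded protein genes 4 of 5 (0.343), for hypoxia and glycolysis 5 of 8 (0.607), for cholesterol synthesis 3 of 10 (0.483) and for p53 targets 3 of 5 (0.762). Pumilio partners and mRNA decay factors had 9 of 14 higher (0.43) and small RNA genes 2 of 9 (0.316). Lists with fewer than 5 listed members had no test: 1 of 2 targeted genes, 2 of 3 cyclin-dependent kinase inhibitors, 1 of 4 erythroid genes, 1 of 4 genes of X inactivation and the Y chromosome, 1 of 3 Hox genes and 0 of 1 protocadherin genes were higher. The Y chromosome genes Eif2s3y, Kdm5d and Uty were listed at 0 in NdcKO, and Xist was higher by 1.44 on the log2 scale of the authors' deposited table. In P1KO these Y chromosome genes were higher than in WT. Their pooled levels, listed or not, were higher in brains labelled P2KO too, at log2 fold changes of 0.98 for Eif2s3y, 0.41 for Kdm5d and 0.27 for Uty. Xist stood at 99.5 FPKM in NdcKO, 36.5 FPKM in WT, 20.2 FPKM in P1KO and 30.7 FPKM in P2KO in the authors' deposited tables. NdcKO thus showed Xist and none of these Y chromosome RNAs, as females alone would. The other groups showed both kinds of RNA, as pools of both sexes would. The labels do not give the sex of the animals, which could not be separated from group.

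Single genes with large finite folds in NdcKO were of varied kinds. The highest in the authors' deposited table were Iltifb, a cytokine gene, at a log2 fold change of 4.51 (q = 0.0353), the vomeronasal receptor gene Vmn2r29 at 4.27 (q = 0.0419) and BB557941 at 4.08 (q = 0.0428), all from WT levels under 1 FPKM. The authors' deposited table also gave log2 fold changes of 3.93 for the ribosomal protein paralog Rpl22l1, 3.75 for Rgs13, a regulator of G-protein signalling, 3.73 for Akr1c19, an aldo-keto reductase, and 3.44 for the cytokine Il22. At the other end the authors' deposited table held Erdr1 (-5.11), the orphan receptor Gpr27 (-4.64), Prr7 (-4.59), the neuroendocrine peptide precursor Pcsk1n (-4.55) and the hypothalamic transcription factor Otp (-3.66) on the log2 scale.

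Brains labelled NdcKO were also compared with each single knockout, although Pum2 was higher in NdcKO than in both. In neither comparison did its rise exceed the upper quartile of genes with like GC content. Against P1KO 8216 genes were listed (4046 higher and 4170 lower) and against P2KO 8115 (4032 higher and 4083 lower). A set of 7122 genes was listed in all 3 NdcKO tables, with NdcKO above the other 3 genotypes for 3501 of them and below for 3621, and none on different sides. The rho with GC content was -0.717 against P1KO and -0.739 against P2KO. Against P1KO 12 of 27 lists passed Fisher's exact test, and against P2KO 5 of 27. Oxidative phosphorylation genes were higher in both (69 of 73, adjusted exact p = 1.33e-15, and 62 of 67, adjusted p = 6.34e-13), and this call held against matched random lists (adjusted p = 0.0048 and 0.0024). This match by bins was not repeated with the nearest genes in length in any NdcKO comparison. The same NdcKO libraries enter both of these comparisons. Endothelial markers were lower in both (10 of 10, adjusted exact p = 0.00883, and 9 of 9, adjusted p = 0.021), with matched adjusted permutation p of 0.0192 and 0.421. Textbook Pumilio targets were higher for 11 of 12 members against P1KO (adjusted exact p = 0.0115) and for 11 of 13 against P2KO (adjusted p = 0.0556), and against P1KO their median of 0.63 lay below the 0.72 of genes matched on GC content and length (adjusted permutation p = 0.686). Against P2KO their median of 0.92 lay above the 0.67 of matched genes, also without passing (adjusted permutation p = 0.465). The authors' deposited tables gave log2 fold changes of Snca of 2.09 against P1KO and 1.77 against P2KO, and of Gt(ROSA)26Sor of 3.92 against P2KO.

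Of the 139 genes listed for P1KO against WT, 62 were listed with the same direction for NdcKO (44.6%, exact 95% interval 36.2% to 53.3%), and 25 with the opposite one. For P2KO the counts were 249 of 391 (63.7%, interval 58.7% to 68.5%) and 32. Because NdcKO listed most genes, independent lists would already share 26.5 higher and 34.4 lower genes with P1KO, and 104 higher and 66.1 lower genes with P2KO, over the 9394 listed genes. In a simulation with the single knockout and NdcKO both unchanged, shared WT libraries gave one direction for 98.1% and 96.9% of the shared genes. In the data the median absolute log2 fold change against WT was 0.87 in NdcKO, 0.07 in P1KO and 0.10 in P2KO. The simulation therefore does not show how much of this agreement came from the WT libraries. In a contrast without any shared library, P2KO over P1KO against NdcKO over WT, 362 of 661 genes were listed with the same direction (54.8%) and 88 with the opposite one, where independent lists would share 165 higher and 123 lower genes. Both contrasts moved with transcript length, with Spearman's rho of 0.346 for P1KO over P2KO and -0.337 for NdcKO over WT. For P2KO over WT it was -0.334. With GC content the rho was 0.20 for P1KO over P2KO and -0.715 for NdcKO over WT. These shares were not adjusted for length or GC content, so they do not show a common effect of the knockouts. In total 32 genes were listed against WT for all 3 knockouts, 17 with one direction (3 higher and 14 lower). The authors' deposited tables gave lower levels of Clic6, Folr1, Kcne2, Slc4a5, a bicarbonate transporter, and Car12, a carbonic anhydrase, in all 3, with log2 fold changes of Clic6 of -0.77, -0.64 and -1.52 in P1KO, P2KO and NdcKO. The choroid plexus list also differed between the knockouts against matched random lists. It was lower in P1KO than in P2KO (6 of 6 members with levels, adjusted permutation p = 0.0425). In NdcKO it was lower than in P2KO (5 of 6, 0.008) and P1KO (4 of 6, 0.048). Whether the dissected brains held unlike amounts of choroid plexus was not tested.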

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

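The tests of GC content, of agreement between the NdcKO tables and of the window around Pum1 were chosen only after the result was seen, as were the count over genes with the same chromosome in GENCODE M21, the test of sex make-up, the comparison with the nearest genes in length and GC content, and the intervals beside the matched genes.

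The 10 genes listed against WT in opposite directions in both single knockouts were each listed in the authors' direct test between P1KO and P2KO as well (all q = 0.00028). The fold between P1KO and P2KO is the difference of their folds against WT, so this listing largely followed from the selection and is no independent support. These genes were chosen after their values were seen. In the authors' deposited table the log2 fold change of P1KO over P2KO was -2.02 for Tuba1c, a tubulin, -1.88 for Cyp2a5, a cytochrome P450, -1.53 for Hddc3, -1.40 for Gm5779 and -1.37 for 6430706D22Rik. It was 0.69 for Id4, an inhibitor of differentiation, 0.93 for the interneuron transcription factor Sp9, 1.12 for Ier5l and 1.53 for Prr7 in the authors' deposited table. Gh was listed at 149 FPKM in P2KO and at 0 in P1KO in the authors' deposited table.

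The first pattern weighed is the large number of genes (8211) listed for NdcKO against WT. Spearman's rho between GC content and log2 fold change was -0.72, so a GC-dependent difference between library sets may account for much of it. A difference in sex make-up was argued against, since in P1KO, where Y chromosome genes differed from WT by 75.9% to 138% of the difference in NdcKO, the median absolute log2 fold change was 7.23% of that in NdcKO (95% interval 6.99% to 7.43%). GC content as the whole cause was not decided. Of 3524 genes with at least a 2-fold difference, 390 (11.1%, exact 95% interval 10.0% to 12.1%) moved against the median of their GC group. The interval was added after the share was seen, and its lower end barely clears the limit of 10% set beforehand. Only the sign of each median was used, although the GC groups with medians of 0.48 and -0.51 had quartiles on both sides of 0. Transcript length, which also moved with this comparison (Spearman's rho = -0.337), was left out. Genotype and the separate collection of NdcKO brains cannot be told apart, since NdcKO lay on one side in 100% of the genes listed in all 3 NdcKO tables, which both predict. The same NdcKO libraries enter all 3 comparisons, which by itself favours one side. Loss of repression through Pumilio sites was not decided either. The coefficient of the Pumilio motif against WT (0.0288) exceeded those of 97.5% of the reordered motifs, whose median was -0.0195. It was below those of P1KO (0.0424) and P2KO (0.0365). Their reordered motifs had higher medians (0.00428 and 0.00275), so the coefficients cannot be ranked between comparisons. Against P1KO and P2KO it was -0.0162 and -0.0188, above those of 58.5% and 54.0% of the reordered motifs (medians -0.0228 and -0.0212). The Pum2 level does not check the NdcKO label.

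The second pattern is the higher level of ribosomal protein and oxidative phosphorylation genes in brains labelled P2KO. These transcripts are short, and the 318 other genes of 913 bases or less, the members' median length, had a median log2 fold change of 0.19. The median of the 140 members was 0.30, above that of genes in the same bins of length and GC content by 0.18 (95% interval 0.13 to 0.25, permutation p = 0.0002, the smallest the draws can give), which argues against a shift of genes with short annotated transcripts as the whole cause. The gap exceeded the limit of 0.1 set beforehand for this match, but it was narrower against the 20 nearest genes, at 0.16 with length alone (0.11 to 0.22) and 0.15 with length and GC content (0.0982 to 0.20, which includes the limit). All these lengths were those of the longest annotated transcript, which may exceed the expressed one. A shift by expressed length was not tested and is not excluded. Composition of the dissected tissue, in view of the pituitary hormone genes, and loss of Pum2, which its level does not check, stay open and were not tested.

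The third pattern is the group of P1KO genes near Pum1 on chromosome 4. DNA of the line in which the Pum1 allele was made may have been carried along with it, since listed genes were over-represented within 20 Mb (odds ratio 4.27, and 3.6 over genes placed on the same chromosome by GENCODE M21) and in P2KO the window was not (odds ratio 0.641). Around Pum2 the window was over-represented for P1KO against P2KO (odds ratio 2.62) but did not pass for P2KO against WT (2.07). The Pum1 window was not over-represented for P1KO against P2KO (odds ratio 0.919), where carried-along DNA should count too. That comparison listed 661 genes and moved with transcript length (Spearman's rho = 0.346), so a few linked genes could go unseen in it. Its odds ratio therefore does not decide on carried-along DNA. A difference private to the WT libraries cannot be told apart from it: 9 of 10 window genes with levels lay on the same side against P2KO (90%, exact 95% interval 55.5% to 99.7%), 6 of them listed there, and 1 of the 16 was listed for P2KO against WT, but 82.8% of listed genes elsewhere lay on the same side too, and the interval, added after the share was seen, includes the limit. A direct effect of Pum1 loss on its neighbours was not tested, and neither were strain variants.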

How the results depend on the processing

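The results matched on GC content and length, without Pum1 and Pum2, without shared libraries, against the median of all levels and with a background of 14606 genes came from tests chosen only after the result was seen. No paired analysis was possible because the deposited tables hold pooled levels and no value per library, and for the same reason leaving out each library and a replicate block were not run. Depth is unknown, so what it limits was not computed.

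With q of at most 0.01, 66 genes were left for P1KO against WT, 150 for P2KO against WT and 318 for P1KO against P2KO. With at least a 2-fold difference the counts were 26, 50, 3586 for NdcKO against WT, 63 for P1KO against P2KO, 3552 for NdcKO against P1KO and 3310 for NdcKO against P2KO. A pseudocount of 1 with at least 0.5 on the log2 scale left 56, 118 and 208 genes for P1KO, P2KO and P1KO against P2KO. These limits remove genes by construction.

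The number of lists passing was 7 for P1KO against WT, 14 for P2KO against WT, 4 for NdcKO against WT, 13 for P1KO against P2KO and 6 for NdcKO against P1KO once matched on GC content and length. This alternative also tests lists with few listed members, through unlisted genes. With direction against the table's median 1 list passed for P2KO against WT and 1 for P1KO against P2KO. With at least a 2-fold difference 0 lists passed for both, which left fewer genes, and 4 passed for NdcKO against P1KO. With q of at most 0.01, 8 lists passed for NdcKO against P2KO; the cause was not tested.

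Reversed means here that a list's median lay on the other side of the median of matched genes than its call. This held for the oligodendrocyte lineage (adjusted permutation p = 0.583) and textbook Pumilio targets (0.686) in NdcKO against P1KO, and cytosolic ribosomal proteins in NdcKO against P2KO (0.604). The gaps to matched genes were 0.13, -0.09 and -0.09. The members kept their own direction, with 9 of 10 lower, 11 of 13 higher and 55 of 68 higher. Of single list results, 54 kept direction and side of the threshold when matched, 10 passed newly, 13 no longer passed and 3 reversed. The counts that kept both were 76 with q of at most 0.01 (3 passed newly and 3 no longer), 84 with at least 1 FPKM (3 no longer), 33 with at least a 2-fold difference (7 no longer) and 88 against the table's median (5 no longer). Without Pum1 and Pum2 the textbook targets passed newly in NdcKO against WT (adjusted exact p = 0.0404) and against P2KO (0.0271).

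Both single knockouts shared 19 genes with q of at most 0.01, 17 of them in one direction, and 7 with at least a 2-fold difference, 5 of them in one direction. Of the genes with at least a 2-fold difference, 30.8% of those for P1KO and 38.0% of those for P2KO were listed with the same direction in NdcKO. Without shared libraries, and with no limit on the fold, the share was 54.8% of the 661 genes for P2KO over P1KO; the cause was not tested. At least a 2-fold difference left 2792 genes in all 3 NdcKO tables, with NdcKO on one side for all 2792. With a pseudocount of 1 the log2 fold change of Pum1 was -1.46 in P1KO and -1.77 in NdcKO against WT, -1.54 in P1KO against P2KO and -1.85 in NdcKO against P2KO, smaller by construction.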

Other observations

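The motif tests of P1KO over P2KO and of NdcKO against both single knockouts had no prediction written beforehand, so these tests count as chosen only after the result was seen, whereas those of P1KO and P2KO over WT were set in advance; genes are not independent replicates.

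After adjustment for GC content and lengths, genes with the Pumilio motif TGTANATA in the 3' UTR may be slightly higher against WT, the hypothesis being a loss of Pumilio repression in the single knockouts, tested for P1KO, and a loss of Pumilio repression in the Pum2 knockouts, tested for P2KO. The coefficient of the motif was 0.0424 on the log2 scale for P1KO over WT, above those of 100% of 200 reordered motifs (highest 0.0285), over 7049 genes of which 1886 carried it. For P2KO over WT it was 0.0365, above those of 100% of the reordered motifs (highest 0.0300), over 6936 genes. The highest reordered motifs, TGTNAATA in P1KO and TGNATATA in P2KO, each also match a form of the Pumilio motif. The reordered motifs are therefore not free of Pumilio sites. Before adjustment the median log2 fold change with and without the motif was 0.0299 and -0.00926 in P1KO, and -0.00315 and -0.00965 in P2KO, so the median with the motif was not above 0 in P2KO. In the comparisons that do not use the WT libraries the coefficient exceeded those of 81.5% (P1KO over P2KO), 58.5% (NdcKO over P1KO) and 54.0% (NdcKO over P2KO) of the reordered motifs. A difference private to the WT libraries therefore stays open, the Pum2 level does not check the P2KO label, and most genes with levels are genes listed in the NdcKO tables.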
